A study of Mus musculus with 2 samples.

How the data were processed

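H3K4me3 ChIP-seq was measured in forebrain from mouse embryos of the B6NCrl strain at embryonic day 10.5, as 2 biological replicates of 1 group, each 1 library from a pool of embryos (69 and 51), with a stated fragment size range of 300 to 500 bp per the labels. The deposited files are 4 peak lists with 10 columns per peak, 1 called on each replicate alone, 1 made from both replicates pooled and 1 called replicated. Per the file headers and the text files beside the lists, the pooled list derives from the alignments of both replicates, the replicated list derives from the pooled list and both replicate lists, and all use build mm10. The aligner, peak caller, thresholds, filters, read numbers and the rule for a replicated peak are not given in the sources used here. The control library that the labels list as possible was not analysed here.

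The authors' fold enrichment (a ratio per peak) is taken as enrichment over background, and each list has its own scale. The authors' -log10 p per peak grows with depth, and the lowest -log10 p was 2.01 in replicate 1 and 2.04 in replicate 2. The deposited -log10 q and display score of each peak were not used, and the summit offset gives the position of the peak's highest point. The authors' fold values describe and rank peaks within a list, and values of both replicates are set side by side only as a description. Checked on the files, all 31093 replicated peaks had the position and fold of a pooled peak. All 26474 pooled peaks that overlapped a peak of each replicate by 50% of either peak were in the replicated list, which held 4605 further peaks. Of the replicated peaks on the chromosomes, 26536 (85.4%) touched both replicate lists, 4298 touched replicate 1's alone, 169 replicate 2's alone and 76 neither.

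The reference was the mouse genome GRCm38, the same build as mm10, with the GENCODE M21 annotation. Peaks ending past a chromosome's end numbered 0. Analyses used chromosomes 1 to 19, X and Y, which left out 18 peaks of replicate 1, 14 of replicate 2, 16 of the pooled and 14 of the replicated list on scaffolds. A gene was called marked when a peak of the replicated list overlapped 1 kb either side of any start of its protein-coding transcripts (21853 genes). An unmarked gene can still have a peak of 1 replicate's own list in these windows, as Th, Gfap, Phox2b and Pou5f1 do in replicate 1. Fold enrichment per gene was the highest among peaks touching these windows, per replicate, with SD over 2 replicates where one is given. CpG observed/expected was taken in 500 bp either side of each start, the highest per gene was kept, and genes were put into 10 deciles. List medians of fold and width were taken over members with a peak in both replicates' own lists. Domains were peaks merged at gaps of up to 1 kb.

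Peak overlap and promoter share were set against 200 seeded random placements of the same intervals on the same chromosome (bedtools 2.31.1 shuffle), with a smallest p of 0.004975. For 25 gene lists with 472 written genes, of which 5 were not matched as protein-coding (Ahsp and the noncoding genes H19, Kcnq1ot1, Meg3 and Airn), marked and unmarked members were compared with all other protein-coding genes by Fisher's exact test, two-sided, with Benjamini-Hochberg adjustment over the lists. Beside it stood 10000 random lists matched on CpG decile, and the same kind of lists drawn from marked genes was used for domain width, with a smallest two-sided p of 2.0e-04. Genes and peaks are not independent replicates, and no p-value across samples was computed, since there is 1 group. Calculations used Python 3.11.15 with numpy 2.4.6, pandas 2.3.3 and scipy 1.17.1.

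The procedures were tested on simulated data. Of 20 planted lists of 20 genes, 18 of them marked, drawn from deciles where marking is incomplete, the CpG-matched test recovered 100% and Fisher's exact test 15%, each with 0 of 80 unplanted lists called, over 21853 genes. With doubled widths, the width test recovered 80% of 20 lists over the 14815 genes marked in the simulation. The simulation adjusted over the planted and unplanted lists together, which were more than the 25 gene lists. The recovery by Fisher's exact test thus holds for the simulated setting and does not carry over directly. The synaptic and the midbrain, hindbrain and spinal cord lists, each with 18 of 20 genes marked, passed that test below (exact adjusted p = 0.0427). The recovery by the CpG-matched test holds for deciles 3 and 4, the source of the planted lists, where 19.5% and 57.0% of genes were marked in the data. It does not carry over to lists whose CpG-matched genes were nearly all marked (96.2% for forebrain patterning genes). Such a list cannot lie above matched lists even when fully marked.

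Gene lists, tests and the rule for named genes were fixed before the data were examined. The rule takes the 15 widest domains with 1 gene each, the one nearest the centre, the 3 marked members of each list with the highest mean fold (6 where under 50% are marked) and up to 3 unmarked members in written order, the 5 genes marked in only 1 replicate with the highest fold, and the 5 genes with the largest centred ratio in each direction. Alternatives changed the window (500 bp and 2 kb), the starts, the peak list, the -log10 p threshold (10), the overlap rule (50% of either or both peaks), the number of peaks, the merging gap (0 bp and 3 kb), the CpG matching, the background genes and the replicate used. A value without a test, other than a count or a ratio per gene, was called moved when it changed by more than 1 SD between the replicates. For the correlation the limit was its 95% bootstrap interval over regions. Counts had a fixed limit on their fold change, and replicate ratios per gene had the SD across genes. Depth could be inferred only in relative terms, from the steps of the low fold values, as the closing section describes.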

Results

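Trimethylation of lysine 4 on histone H3 (H3K4me3), a mark found at the starts of genes, was profiled by chromatin immunoprecipitation and sequencing (ChIP-seq) in the forebrain of B6NCrl mouse embryos at embryonic day 10.5, when the forebrain wall consists mostly of dividing neural progenitors and the earliest neurons are being born. Both biological replicates came from pools of male and female embryos, 69 embryos for replicate 1 and 51 for replicate 2. The data form 1 group of 2 samples with no second tissue, age or treatment, so the comparisons below are between the replicates and between groups of genes within this tissue. Replicate 1's list held 48535 peaks over 53.8 Mb and replicate 2's list held 33341 peaks over 41.8 Mb. The authors' list made from both replicates together held 46944 peaks, and their replicated list held 31093 peaks over 51.5 Mb. The number of reads behind each list is not given in the sources used here. Every fold enrichment below is the authors' own value for a peak.

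The mark lay chiefly at the starts of protein-coding genes. In the replicated list, 48.7% of peaks fell within 1 kb of a protein-coding transcription start, against a mean of 4.49% when the same intervals were placed at random 200 times on their chromosomes (highest placement 5.04%, permutation p = 0.004975, the smallest these placements can give). These promoter peaks made up 73.0% of the covered bases. They had a median fold enrichment of 47.8 and a median width of 2276 bp. Peaks at the starts of other gene types made up 5.86% of the list, exonic peaks 9.11%, intronic peaks 15.4% and intergenic peaks 20.9%. Away from starts the peaks were weak, with median fold enrichments of 4.43 in exons, 3.72 in introns and 5.14 between genes, and 10.3% of intronic and 25.5% of intergenic peaks reached a fold of 10. The promoter share was 35.0% in replicate 1 and 47.5% in replicate 2. With equal numbers of peaks it was 46.1% and 47.5%, and at -log10 p of 10 or more it was 60.9% and 69.6%.

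The replicates marked the same strong regions and differed at weak ones. Of replicate 2's peaks on the chromosomes, 92.8% (30914 of 33327) overlapped a peak of replicate 1 by at least 1 bp, and 57.2% of replicate 1's peaks (27749 of 48517) overlapped replicate 2. Random placement gave means of 4.11% and 3.01% (permutation p = 0.004975 for each, the smallest these placements can give). Across the 26660 regions called in both lists, the highest fold enrichment had a Spearman correlation of 0.949 between the replicates and a Pearson correlation of 0.969 on the log2 scale. These correlations are across regions, which are not independent replicates. The SD of the centred log2 ratio was 0.42. Among the 10002 shared regions with a mean fold under 10 the Spearman correlation was 0.685, and among the 16658 stronger regions it was 0.860.

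**Figure D1:**
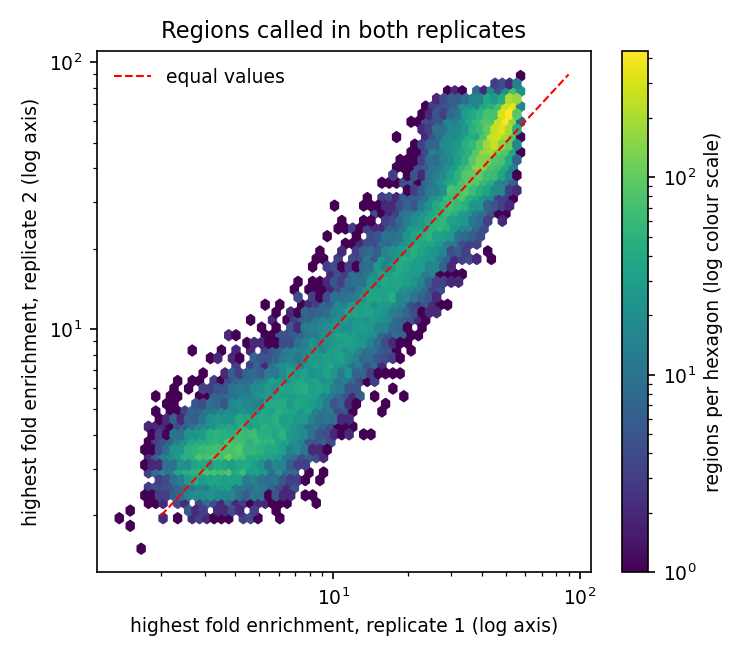
Highest fold enrichment of each region called in both replicates, replicate 1 on the horizontal and replicate 2 on the vertical log axis; colour gives the number of regions per hexagon on a log scale and the dashed line marks equal values. The 26660 regions follow the line (Spearman 0.949), and the strongest regions lie above it, with replicate 1's values ending at 57.5 and replicate 2's at 88.8.

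Peaks found in 1 replicate were narrow, weak and mostly away from promoters. Replicate 1 had 20768 such peaks (42.8% of its list), with a median fold of 2.76 (quartiles 2.57 and 3.20), a median width of 231 bp and a promoter share of 9.60%. Introns held 41.0% of them. Its 27749 shared peaks had a median fold of 19.7, a median width of 1412 bp and a promoter share of 54.0%. Replicate 2 had 2413 peaks of its own (7.24%), with a median fold of 3.03, a median width of 203 bp and a promoter share of 12.7%. In both lists, 0 peaks without a partner under the 1 bp rule reached a fold of 10. When an overlap of 50% of both peaks was required, peaks without a partner numbered 25438 (52.4%) in replicate 1 and 10248 (30.7%) in replicate 2, of which 270 and 340 reached a fold of 10, and 69.3% of replicate 2's peaks were shared. With 1 library on each side, these differences carry no test.

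H3K4me3 marked the promoters of most protein-coding genes. A peak of the replicated list lay within 1 kb of a start in 14643 of 21853 genes (67.0%). Replicate 1's own list gave 14812 genes and replicate 2's gave 14574, with 14530 marked in both, 282 in replicate 1 alone and 44 in replicate 2 alone. Marked genes followed promoter CpG content. The share marked rose from 1.42% in the lowest decile of CpG observed/expected through 19.5% in decile 3, 57.0% in decile 4 and 91.7% in decile 5 to 99.7% in the highest. In decile 4 the replicates gave 58.9% and 56.0%, and in the highest decile both gave 99.7%.

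**Figure D2:**
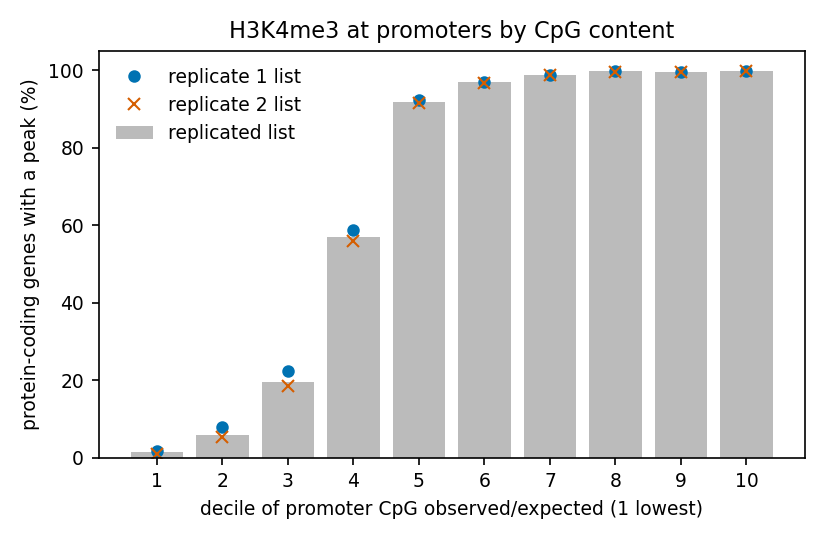
Percent of protein-coding genes with a peak within 1 kb of a start, by decile of promoter CpG observed/expected; bars show the replicated list, dots replicate 1 and crosses replicate 2. The share climbs from 1.42% in decile 1 to 91.7% in decile 5 and 99.7% in decile 10, with the replicates close together.

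Genes of forebrain identity and of neural progenitors all carried a peak near a start, a result that depended on counting any part of a peak. All 22 forebrain patterning transcription factors carried a peak, as did all 16 ventral forebrain and hypothalamic genes and all 20 progenitor genes (Fisher's exact test against the other protein-coding genes, two-sided, Benjamini-Hochberg over 25 lists, adjusted p = 8.54e-04, 0.00393 and 0.00119). Among the patterning genes, the nuclear receptor gene Nr2f1 had a fold enrichment of 51.8 in replicate 1 and 68.5 in replicate 2, Tcf7l2, which encodes a Wnt pathway transcription factor, 52.0 and 67.9, and the cortical regulator Emx2 51.6 and 62.9. Among progenitor genes, the RNA-binding protein gene Msi1 reached 45.5 and 81.4, the Notch effector Hes5, whose domain also covers the start of Pank4, 54.4 and 68.3, and the receptor gene Notch1 54.2 and 65.4. The ventral genes had a list median of 20.9 for the mean of both replicates. The homeobox gene Dlx2 stood highest among them at 38.4 and 47.6, followed by Dlx5 at 29.3 and 26.4 and Dlx1 at 30.8 and 24.2. When the peak's summit had to lie within 1 kb of a start, an alternative added after the data were seen, 17 of 22 patterning, 12 of 16 ventral and 16 of 20 progenitor genes were marked and the 3 calls ended (exact adjusted p = 0.374, 0.716 and 0.353). The patterning and ventral lists then lay below CpG-matched random lists (permutation adjusted p = 0.0242 and 0.0170). This rule counts each peak by its 1 highest point, so a wide peak over a start fails when that point lies farther off. Both lists had wide domains (medians of 14.3 and 5.22 kb against 2.59 and 2.65 kb in matched lists). Under the main rule, 21 of 22 patterning genes reached a fold of 10 in both replicates. The summit rule therefore cannot tell fewer marked starts from wider peaks.

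Most neuronal genes in the lists carried the mark. All 21 genes of early neuronal differentiation carried the mark (exact adjusted p = 8.54e-04), with a list median of 26.2, led by the RNA-binding protein gene Elavl4 at 44.6 and 54.9, the microtubule protein gene Map2 at 47.4 and 50.6 and the proneural gene Ascl1 at 46.1 and 51.1. Of 20 genes of mature synapses and neurotransmitters, 18 were marked (exact adjusted p = 0.0427), with a list median of 21.3. The vesicle fusion gene Snap25 had 39.7 and 30.9, the calcium sensor gene Syt1 41.1 and 27.4, and the receptor subunit gene Gabra1 34.9 and 32.3, while Th and Vip were unmarked. The early neuronal call ended under the summit rule (16 of 21, exact adjusted p = 0.477), and the synaptic call ended with replicate 2's own list, with a peak required in both replicates and with the 5'-most start alone (exact adjusted p = 0.144, 0.143 and 0.228). Genes of mature glia did not pass the test, with 8 of 14 marked (exact adjusted p = 0.513). The glutamate transporter gene Slc1a2 and the myelin genes Mbp and Cnp carried the mark, and Gfap, S100b and Plp1 did not. For comparison, constitutively used genes were all marked: 18 of 18 housekeeping genes, 32 of 32 ribosomal protein genes, 23 of 23 cell cycle genes and 24 of 24 genes of H3K4 and Polycomb chromatin enzymes (exact adjusted p from 2.54e-05 to 0.00288), with list medians of 50.8, 56.2, 52.2 and 56.4. Ywhaz reached 51.7 and 79.0, Rpl19 56.4 and 81.4, Cdc20 54.9 and 77.3, and the H3K4 methyltransferase gene Kmt2d 54.5 and 76.1. All 23 genes of secreted signals were marked (exact adjusted p = 6.06e-04), led by Nog, which encodes a BMP antagonist, at 46.8 and 57.9.

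Genes of other cell types that the dissection could hold differed widely. All 18 genes of head mesenchyme and neural crest were marked (exact adjusted p = 0.00288), with Prrx2 at 45.5 and 57.9, Prrx1 at 30.7 and 49.9 and Msx1 at 38.2 and 39.9; under the summit rule 16 of 18 were marked and the call ended (exact adjusted p = 0.0746). All 16 endothelial and pericyte genes were marked (exact adjusted p = 0.00393), at a list median of 11.9; the vascular receptor gene Kdr reached 43.8 and 51.4. Replicate 2's own list marked 14 of these 16 and peaks with a -log10 p of 10 or more marked 11, each of which ended the call (exact adjusted p = 0.152 and 1). Of the midbrain, hindbrain and spinal cord transcription factors, 18 of 20 were marked (exact adjusted p = 0.0427), at a list median of 15.7, with Isl1, Mafb and Egr2 highest and Phox2b and Evx2 unmarked; with peaks of -log10 p 10 or more the call ended (17 of 20, exact adjusted p = 0.128). Erythroid and early blood genes did not pass the test (9 of 15, exact adjusted p = 0.685): the regulators Runx1, Klf1 and the receptor gene Epor were marked, and the globin genes Hbb-y, Hba-x and Hba-a1 were not in the replicated list. Each replicate's own list did hold a peak near a start of Hba-x. Microglial and macrophage genes were marked less often than other genes (4 of 16, exact adjusted p = 0.00161), but about as often as CpG-matched genes (25% against 24.6%). Of the microglial genes, Hexb, which encodes a lysosomal enzyme, alone exceeded a fold of 10 in both replicates. Surface ectoderm (11 of 16, exact adjusted p = 1), eye (9 of 14, exact adjusted p = 0.816) and muscle and heart genes (8 of 16, exact adjusted p = 0.241) did not pass the test, although the muscle list fell below other genes with a 500 bp window (5 of 16, exact adjusted p = 0.00892) and under the summit rule (exact adjusted p = 0.0166). Among the eye genes, Pmel stood highest, but it shared its peak with the neighbouring cell cycle gene Cdk2.

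The lists farthest below other genes belonged to lineages outside the embryonic brain. None of the 14 liver genes was marked (exact adjusted p = 2.25e-06), including Alb, Afp and Apoa1. The germ line list had 2 of 18 genes marked (exact adjusted p = 1.18e-05), Dazl at 22.0 and 21.7 and Tdrd1 at 3.48 and 3.50, while Ddx4, Mael and Sycp1 were not in the replicated list. Among olfactory receptor genes, 3 of 1092 were marked, namely Olfr94, Olfr658 and Olfr1033. Pluripotency genes did not pass the test (12 of 16, exact adjusted p = 0.685): Lin28a, Sall4 and Klf4 had mean folds of 55.1, 54.4 and 42.8, and Pou5f1, Nanog and Dppa4 were unmarked. Of 16 imprinted genes, 15 were marked (exact adjusted p = 0.0427), led by Gnas and Igf2r, with Ndn unmarked; with the 5'-most start alone 12 were marked and the call ended (exact adjusted p = 0.505).

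Much of this ordering went with promoter CpG content. Against 10000 random lists matched on CpG decile, 5 of the 25 lists stood apart after adjustment. The early neuronal list (100% marked against a mean of 75.2% in matched lists, permutation adjusted p = 0.00125) and the endothelial list (100% against 64.5%, permutation adjusted p = 0.0020) lay above, and the Hox genes (64.1% against 92.3%), the germ line genes (11.1% against 85.7%) and the olfactory receptors (0.275% against 8.51%) lay below (permutation adjusted p = 0.00125 for each). The endothelial call ended with replicate 2's own list, with a peak required in both replicates and at -log10 p of 10 or more (permutation adjusted p = 0.102, 0.0892 and 1), and the early neuronal call ended under the summit rule (permutation adjusted p = 1). The blood list rose above matched lists in the pooled list, in replicate 2's own list and under the summit rule (permutation adjusted p = 0.00125, 0.0050 and 0.0457), and the pluripotency list with the 5'-most start and the liver list in the pooled list fell below them (permutation adjusted p = 0.0400 and 0.0421). The forebrain, progenitor, housekeeping and ribosomal lists did not, since 94.7% to 99.4% of CpG-matched genes were marked too. When only genes in CpG deciles 6 to 10 were used, 98.9% of the other genes were marked. No list could lie above by Fisher's exact test there, even with every member marked, and 0 did. Below lay 2 lists: 20 of 28 Hox genes (exact adjusted p = 5.19e-09) and 2 of 11 germ line genes (exact adjusted p = 2.22e-15) were marked. These tests run across genes, which are not independent replicates.

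Domain width set several gene lists apart from CpG-matched lists where presence of a peak did not. For lists whose matched genes were nearly all marked, presence could not have set them above. The lists were not tested against each other. Peaks of each replicate were merged at gaps of up to 1 kb, and a gene's width was the mean of both replicates. The 14530 genes marked in both had a median width of 2.53 kb (95th percentile 6.47 kb), and widths correlated between the replicates (Spearman 0.904, across genes). Forebrain patterning transcription factors had the broadest domains, at a median of 14.3 kb against 2.59 kb in CpG-matched random lists, followed by neural progenitor genes at 8.23 kb against 2.67 kb and head mesenchyme and neural crest genes at 7.16 kb against 2.42 kb. Secreted signals (5.37 kb), ventral forebrain (5.22 kb), imprinted (5.12 kb), housekeeping (4.86 kb), cell cycle (4.61 kb), ribosomal (4.03 kb) and early neuronal genes (3.91 kb) were also broader than matched lists (random-list test, two-sided, Benjamini-Hochberg adjusted p from 5.11e-04 to 0.00125). The order of the lists depended on the gap: with a gap of 0 bp the ventral median was 3.23 kb, the secreted signal median 3.19 kb and the midbrain and hindbrain median 1.87 kb. With 3 kb the ventral median was 13.1 kb, above the 10.6 kb of progenitor genes, and the midbrain and hindbrain median was 6.09 kb. Midbrain and hindbrain transcription factors passed narrowly (3.57 kb, permutation adjusted p = 0.0437), and that call ended in either replicate alone (permutation adjusted p = 0.462 and 0.0881) and in the replicated list (permutation adjusted p = 0.175) and turned around when only touching peaks were merged. The synaptic, glial, chromatin enzyme, pluripotency, blood, microglial, endothelial, ectodermal, eye, muscle and olfactory receptor lists did not pass the test, and the germ line and liver lists had too few marked genes. Chromatin enzyme genes passed as broad with only touching peaks merged, with a gap of 3 kb and without CpG matching (permutation adjusted p = 0.0348, 0.0400 and 0.0356), and blood genes passed with a gap of 3 kb (5.81 kb, permutation adjusted p = 0.0483). Pluripotency genes passed as narrow in the replicated list and in replicate 1 alone (permutation adjusted p = 0.0176 and 9.20e-04), microglial genes with a gap of 0 bp (permutation adjusted p = 0.0348), and glial, muscle and olfactory receptor genes without CpG matching (permutation adjusted p = 0.00624, 0.00601 and 0.00335).

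**Figure D3:**
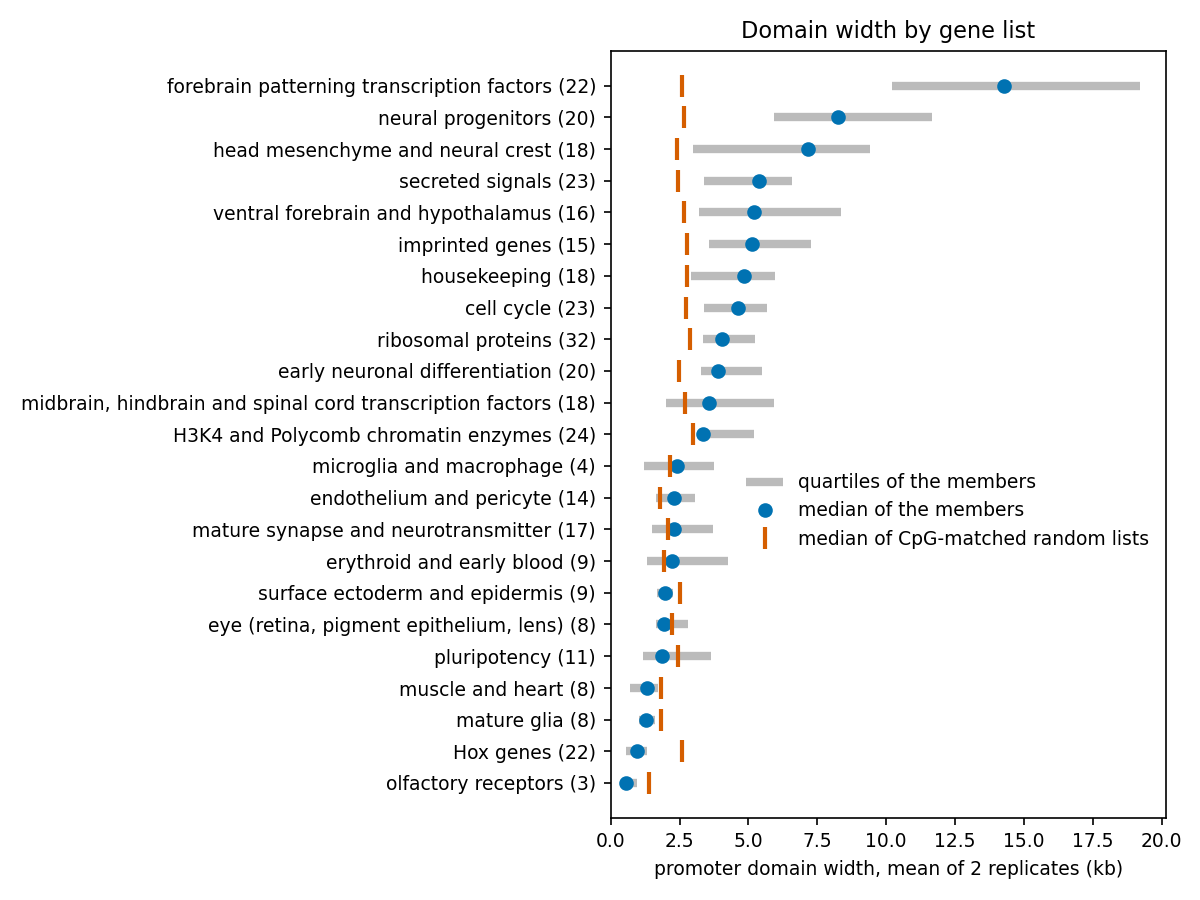
Promoter domain width by gene list, in kb, as the mean of 2 replicates; dots are medians, grey bars the quartiles of the members with a width in both replicates, orange ticks the median of CpG-matched random lists, and the number of members with a width in both replicates stands beside each name. Forebrain patterning transcription factors reach a median of 14.3 kb and Hox genes 0.94 kb, on either side of matched lists near 2.6 kb.

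The 15 widest domains included several on developmental transcription factor genes. Among them, the nuclear receptor gene Nr2f2 on chromosome 7 (70351944 to 70366735) had 28.8 kb ± 1.49 (SD, n = 2), Sox2, a progenitor transcription factor gene on chromosome 3, 27.5 kb ± 6.05, and Pou3f3 on chromosome 1 26.5 kb ± 6.49. The eye and forebrain regulator Pax6 on chromosome 2 (105668900 to 105697364) had 24.1 kb ± 0.23, Nr2f1 23.7 kb ± 11.3, Emx2 19.8 kb ± 2.38, Six3 19.2 kb ± 0.08 and Lhx2 19.2 kb ± 6.93. A domain of 26.5 kb ± 4.54 named for the predicted gene Gm43517 on chromosome 12 also covered the start of Foxg1, which encodes a telencephalic transcription factor, and that of Zic4 (24.9 kb ± 1.15) covered Zic1. Skida1's domain (22.9 kb ± 1.55) covered the start of Mllt10, and in replicate 1 those of Zic2 (20.9 kb ± 9.25) and of the H3K27 demethylase gene Kdm6b (24.0 kb ± 8.66) covered Zic5 and 3 further genes respectively. Bahcc1 had 20.1 kb ± 0.11. The widest of all, at Midn on chromosome 10, measured 39.8 kb ± 19.7 and differed between the replicates (53.7 and 25.8 kb); in replicate 1 it covered the starts of 5 further genes. With only touching peaks merged, it measured 8.72 kb.

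Hox genes, the homeobox genes that pattern the hindbrain and trunk, had narrow domains. They were marked at 25 of 39 starts, with a list median fold of 5.79 and a median width of 0.94 kb against 2.60 kb in matched lists (permutation adjusted p = 5.11e-04). Of the 4 clusters, Hoxd had 8 of 9 genes marked, Hoxa 7 of 11, Hoxb 6 of 10 and Hoxc 4 of 9. The strongest were Hoxa1 at 40.6 and 37.9, Hoxd1 at 24.1 and 19.6 and Hoxa7 at 18.7 and 14.9, while Hoxa3, Hoxa6 and Hoxa9 were unmarked in the replicated list.

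**Figure D4:**
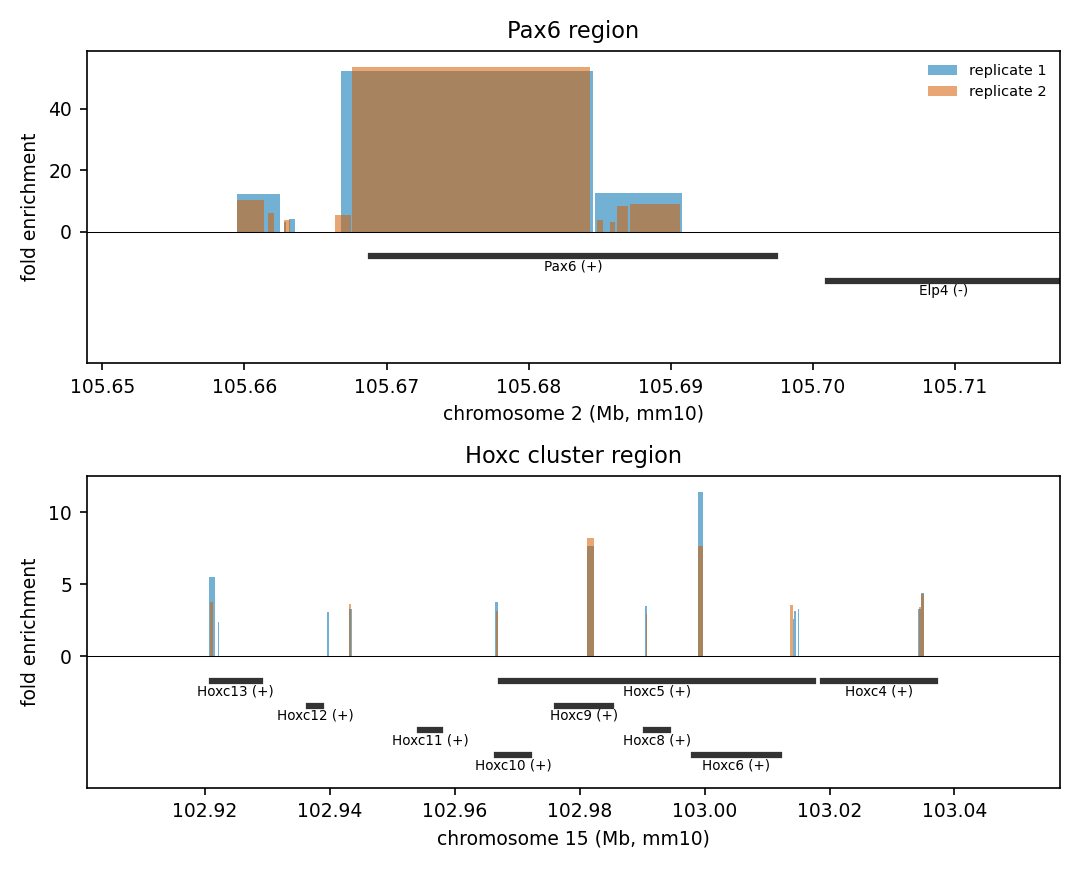
Peaks of both replicates over Pax6 on chromosome 2 and over the Hoxc cluster on chromosome 15, with position in Mb of mm10 on the horizontal axis, fold enrichment on the vertical axis (the scales differ between panels), each bar 1 peak drawn at its width, and genes as dark lines with their strand. Pax6 carries a broad domain of 24.1 kb with folds of 52.1 and 53.5, and the Hoxc cluster carries short peaks with folds of up to 11.4. In the replicated list, 4 of its 9 genes have a peak within 1 kb of a start, with a highest fold among them of 5.51 (Hoxc13, replicate 1). The peak with a fold of 11.4, in replicate 1, lies within Hoxc6 and within 1 kb of the start of the gene as drawn. Hoxc6 is unmarked because only starts of protein-coding transcripts counted.

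Summits lay just downstream of transcription starts. The strongest peak at a start had its summit a median of 169 bp downstream in replicate 1 (quartiles 67 and 312 bp) and 165 bp in replicate 2 (quartiles 67 and 285 bp), and 83.0% and 83.6% of these summits lay downstream. With the 5'-most start of each gene alone, the medians were 256 and 235 bp.

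Few genes differed in kind between the replicates. The genes marked only in replicate 2 were weak, the highest being Gpr182 at a fold of 7.26, followed by Armc12 at 4.67 and Aqp6, Armc4 and Nat1 at 3.82. Those marked only in replicate 1 at the highest folds, AC141477.1, Nup160, Rap2b, Hist1h1d and A930004D18Rik (38.4 to 49.9), were in the replicated list. Every replicate 1 peak with a fold of 10 or more overlapped a replicate 2 peak, which here did not reach within 1 kb of a start of these genes. In replicate 1, AC141477.1 shared its domain with Pcnt, Rap2b with B430305J03Rik, and A930004D18Rik with Skida1 and Mllt10. Among genes marked in both, after centring on the median ratio, Acaa1a and Myd88 (log2 ratio 1.40, from folds of 17.7 and 53.5), Lrrc42 and Hspb11 (1.37) and Eif4e2 (1.35) stood highest in replicate 2. The first 4 form pairs that share a peak. In the other direction stood Gm48551, Fam83e, Nhlh1, Gm17349 and Tulp2. Taking the highest fold in the merged domain in place of the peak in the window, a choice made after seeing the data, reduced the difference at Gm48551 from -4.56 to -0.30 on the log2 scale and at Nhlh1 from -3.21 to -1.24 and turned it around at Gm17349 (-3.13 to 0.12), while Fam83e (-3.99) and Tulp2 (-3.05) stayed apart. In replicate 1, however, Fam83e's domain also covered the starts of Sphk2, Rpl18 and Spaca4, and Tulp2's those of Gm45808 and Dhdh. In replicate 2 neither gene shared its domain, so the values compared can belong to different peaks. With 1 library on each side, none of these differences was tested.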

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

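The entry in this part was looked for by a rule fixed before the data were examined, and all tests of explanations named in it were chosen after the result was seen. The replicated list held 14 peaks on unplaced or unlocalized scaffolds of the genome, a part that no comparison above used and whose signal drew attention for that reason. These peaks lay on 6 scaffolds and had a median fold enrichment of 12.6, with 8 at a fold of 10 or more and a highest value of 55.7. Replicate 1's list held 18 such peaks and replicate 2's also 14. The genes on these scaffolds were not analysed here.

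Replicate 1's list held 1.46 times as many peaks as replicate 2's, while the numbers with a fold of 10 or more were close (17051 and 16376, ratio 1.04). The low fold values fell on regular steps, of 0.184 in replicate 1 and 0.294 in replicate 2, and 48.0% and 39.3% of values lay on such a grid against 2% by chance. If the values were pileup plus 1 over background plus 1, an assumed formula, the steps would give a ratio of background reads of 1.85, or a depth ratio of 2.08 per bp if the shortest peak of each list (160 and 180 bp) is also taken as its read extension; either could account for the extra weak peaks. Lower enrichment in replicate 1 was left open, because its test (a median log2 difference of 0.34 in pileup over background, SE 0.003, 16658 regions) was void: the highest pileups under the same formula were about equal (312 and 301) and point to a ceiling, and lower enrichment need not add peaks. No biological explanation was tested.

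Neuronal genes (37 of the early neuronal and synaptic lists) lay lower in replicate 2 relative to replicate 1 than constitutive genes (73 of the housekeeping, ribosomal and cell cycle lists, without the chromatin enzymes), with a difference in median log2 ratio of -0.78 ± 0.10 (bootstrap SE over genes). Removing the trend on fold level brought it to -0.30 ± 0.08, so that a compressed scale among the highest folds could account for most of it. The rest lay more than 2 SE from 0, but this cannot exclude fold level as the whole cause. The trend was fitted on the mean of both replicates' folds, which carry error, and the SE runs over genes with 1 library on each side. Removing promoter GC content left -0.68 ± 0.11, which excluded GC as the main cause by the criterion set, and removing both left -0.31 ± 0.08. No biological explanation was tested.

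Among genes in the upper 5 CpG deciles, 120 had no replicated peak. Repeated sequence could account for part of this. At least 10% of the 31-mers lay elsewhere in the genome at 68 of them (56.7%, 95% interval 47.3 to 65.7), against 10 of 120 marked promoters (8.33%). The interval includes 50%, and the criterion was read on the point value after it was seen. The 10% cutoff also takes in promoters of mostly unique sequence, such as those of Naa11 (13.4% repeated) and Pcdha5 (23.0%). It therefore does not show that short reads could not be placed. Loss to the authors' replication rule (10%, upper limit 16.8) and a peak within 5 kb of a start (15%, upper limit 22.7) were each too rare to explain most of the 120 genes. No biological explanation was tested for the 32 genes (26.7%) that none of these covered.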

How the results depend on the processing

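Alternatives were fixed before the data were examined, apart from those with the summit near a start, with domains of single genes and with the domain's highest fold, which were added after the data were seen. Marked-gene counts stayed between 14068 and 14852, and the overlap of the lists and the promoter shares kept their calls throughout. Lists with broad domains numbered 10 to 13, against 11, with midbrain and hindbrain, chromatin enzyme and blood genes changing their call. Peaks found only in replicate 1 fell to 3936 at a -log10 p of 10 or more and to 7394 with equal numbers of peaks, by construction of fewer peaks. Those only in replicate 2 fell from 2413 to 107 at that threshold, where both lists were cut. With equal numbers they rose to 3790 (11.4%), since only replicate 1's list was cut and lost peaks that had been partners. The replicate correlation was 0.975 with -log10 p in place of fold, 0.909 at -log10 p of 10 or more and 0.946 with equal numbers. With CpG deciles 6 to 10 as background, 98.9% of the other genes were marked, so that even a fully marked list could not lie above. This left 0 lists above and 2 below other genes, and 0 above matched lists. There the difference in marked share from other genes turned for midbrain and hindbrain (-4.46 points), microglial (1.0985), blood (1.0985), glial (1.0984), eye (1.0987) and muscle genes (1.0986). Only list members within these deciles were counted, which leaves fewer genes per list. The positive values mean that every remaining member was marked, and they do not reverse the result for the full list. Further turns were all in lists without a call in the main setting: ectodermal genes with 500 bp (-3.95), the 5'-most start (-1.88), a peak in both replicates (-10.2), -log10 p of 10 or more (-3.66) and the summit rule (-21.2); pluripotency genes with the 5'-most start (-8.13) and -log10 p of 10 or more (-3.66); Hox genes with 2 kb (4.05) and the pooled list (8.98); and blood genes with the pooled list (5.37). With 1 replicate left out, the share ranged from -10.4 to 0.971 points for ectodermal, -9.55 to 3.65 for glial and -7.73 to 1.45 for Hox genes. Lists above matched lists fell to 1 with a peak in both replicates and to 1 at -log10 p of 10 or more, the endothelial list being lost in each. With the summit near a start, 9 lists lay above other genes, with the forebrain patterning, ventral, progenitor, early neuronal and head mesenchyme lists losing their call, and 5 below matched lists, the patterning and ventral lists being new. A wide peak can fail this rule while covering a start. The top CpG decile reached 99.9% with a 2 kb window, the lowest 0.869% with 500 bp, 2.06% with 2 kb and 1.97% in the pooled list, and decile 4 59.2% in the pooled list. Narrow lists numbered 3 with a gap of 0 bp, 2 in the replicated list, 4 without CpG matching and 2 to 2 with 1 replicate left out, against 1 (Hox genes throughout; also 3 germ line genes without replicate 1, too few for a test with both replicates, and pluripotency genes without replicate 2), and with a gap of 0 bp midbrain and hindbrain domains turned to -0.55 kb against matched lists. Widths of lists without a call turned with a gap of 0 bp for blood (-0.14 kb) and microglial genes (-0.94), with 3 kb for synaptic (-0.011) and eye genes (0.46), in the replicated list for eye genes (0.011), without CpG matching for synaptic (-0.24), blood (-0.31), microglial (-0.18) and endothelial genes (-0.24), and with domains of single genes for microglial genes (-1.02). With 1 replicate left out they ranged from -0.016 to 0.74 kb for blood, -0.72 to -0.54 for microglial and -0.20 to 0.14 for eye genes. Summits lay at 245.5 bp with the 5'-most start and midpoints at 207.5 bp, against 167 bp. The log2 ratio of Gm17349 turned to 0.12 with the domain's highest fold. Of the differences in marked share, 200 kept direction and call, 27 weakened, 3 grew and 19 turned. Of the domain widths, 158 stayed, 21 moved, 9 grew, 3 weakened and 15 turned. With 1 replicate left out, lists above other genes ranged from 12 to 14, marked genes from 14574 to 14812 and decile 4 from 56.0% to 58.9%. Where the construction does not show it, the cause was not tested. No paired analysis was possible because the series holds 1 group. The depth of the lists limits what weak peaks can show.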

Other observations

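The names in this paragraph were picked after the values were seen, apart from the noncoding genes of the imprinted list, and no test was run on them. Of 10155 noncoding genes, 7434 lay more than 5 kb from a coding start, and 975 of these (13.1%) carried a peak of the replicated list. The nuclear RNA gene Malat1 on chromosome 19 (5795690 to 5802672 in mm10) had the highest mean fold enrichment, 63.0 ± 10.6 (SD, n = 2), and Dleu2 and Gm27017, which share a peak, had 59.8 ± 15.6. The 4 noncoding genes written in the imprinted list were marked, with Kcnq1ot1 at 34.6 ± 6.59, Airn at 31.4 and 30.6 in the 2 replicates, Meg3 at 24.9 ± 8.71 and H19 at 13.0 ± 2.62. On the X chromosome, Xist, the RNA gene of X inactivation, had 15.4 ± 1.04 and its antisense gene Tsix 19.0 ± 0.20, from pools of both sexes. Sox2ot (51.7 ± 11.3) had the values of Sox2, whose peak it shares, and Six3os1 (44.3 ± 13.1) those of Six3. Dlx6os1 had 21.7 ± 3.39. The Hox cluster transcripts Hotair and Hottip were unmarked.

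Over marked Hox genes with a peak in both replicates' own lists, median fold enrichment was 13.3 in Hoxa, 10.04 in Hoxd, 5.15 in Hoxb and 3.91 in Hoxc (6, 7, 4 and 4 genes), and 8 Hox genes reached a fold of 10 in both replicates. The CpG-rich genes without a peak that neither repeated sequence nor a nearby or discarded peak covered numbered 32, and 6 of them belong to the germ line list, among them the meiotic genes Sycp1, Sycp3 and Hormad1. Hoxc11 was the only Hox gene of that set. On the X chromosome 52.1% of protein-coding genes were marked, and on the Y chromosome 4 of 183. Replicate 1's list held 1.60 peaks for each peak of replicate 2 on chromosome 19, 1.59 on chromosome 17 and 1.17 on the X chromosome.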
